A study of Mus musculus with 2 samples.

How the data were processed

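Total RNA from mouse CD8 T cells was labelled with biotin by a whole-transcript sense-target method, per the labels' protocols, and measured on 1 array per condition. Both cultures were kept under Tc1 cytokines, and cholesterol was added to 1 of them, per the labels' protocols. Tc1 cells are CD8 T cells driven by type 1 cytokines toward interferon gamma production and killing. The dose, duration and vehicle of the cholesterol treatment, the mouse strain and the tissue of origin are not given in the sources used here. There was 1 array in each group, so no difference below has a replicate error or a p-value.

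The values deposited by the authors are signal intensities on a linear scale, 1 per probe set and array, for 28846 probe sets. The software, the background correction and the normalization behind them are not given in the sources used here. The series value table held intensities identical to those of the authors' annotated table, with a largest difference of 0, so it gave no separate alternative. The authors also deposited a ratio of the cholesterol signal to the untreated signal for 22206 probe sets, and this ratio equalled the quotient of the deposited signals for all 22206 within a tolerance of 1e-09. The annotated table gives gene symbols, but no genome build, and no coordinates were used here.

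The 22206 annotated probe sets were taken as gene-level. Of these, 27 had symbols turned into dates, 3 had no symbol and 1 listed a symbol pair, and these were left out. The remaining 22175 probe sets named 21877 genes. For the 201 genes with more than 1 probe set, the probe set with the highest mean log2 signal was used. Signals were converted to log2, and the difference was taken as cholesterol minus untreated. A gene entered the counts when its brighter array reached the median of all gene-level values, a signal of 47.4, and 11327 genes did so. The remaining 6640 probe sets are controls, of which 5222 are named as negative controls. The 95th percentile of the negative controls was a signal of 130.3 on the untreated array and 121.8 on the cholesterol array. Detection calls per gene were not used here. Of the genes past the brightness filter, 31.2% lay at or below these percentiles on both arrays, and their levels are read with that limit. A signal close to the background leaves the size of a fold uncertain. For a named gene within the range of the negative controls, at or below their 95th percentile, on 1 array, the fold is therefore given as at least the brighter signal over that percentile of the other array, and no fold is given where both arrays lie within it. This rule was set after seeing the data, and it left 48 of the 82 genes named by the rule below with an exact fold. The folds given as at least a value make no allowance for noise between the arrays. Log2 differences and counts of genes past 1.5-fold or 2-fold are those of the deposited signals and carry no such bound. Over 67 genes with a pair of probe sets past the filter on average, the log2 differences of the brightest pair disagreed by a median of 0.14 and a 95th percentile of 0.68.

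Before the data were examined, 27 gene lists, a size threshold of 2-fold, most of the alternatives and a rule for the genes to name were fixed. The rule took the 10 genes with the largest difference in each direction past the brightness filter, leaving out model-number genes, RIKEN clones, microRNA and small nucleolar RNA genes. It also took the 2 members of each list with the largest absolute difference past the filter, and a set of sterol, effector, checkpoint and CD8 genes whatever their values. The rule named 82 genes, a few of which are not reported here. Other list members named in the text were chosen after their values were seen. The lists hold 446 measured memberships of 442 genes, 9 listed genes had no matching symbol, and Cd244a was matched as Cd244 through the synonyms of the GRCm38.p6 RefSeq annotation. Each list's median log2 difference was set against 10000 random gene lists of the same size matched on mean signal in 20 bins. The resulting percentile describes these 2 arrays. It is not a p-value, and co-regulated genes of a list can move together more than randomly drawn genes do. By chance, 1.35 of the 27 lists would lie outside the central 95%.

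The procedures were tested on simulated data with the signal levels of the 21877 genes of the comparison of cholesterol with untreated cells. With 50 genes per fold size, the 2-fold rule recovered 2% of genes changed 1.5-fold, 88% of those changed 2.5-fold and 100% of those changed 4-fold, and it called 5 of 11080 unchanged genes. Of 1000 unchanged lists of 20 genes, 5.9% lay outside the central 95%, and 98.5% of lists shifted by 0.3 on the log2 scale lay above it. The simulated noise was drawn from normal distributions, with a spread set by the median absolute difference between these 2 arrays at each signal level. Tails beyond a normal distribution were therefore not simulated, and the number of unchanged genes called may be too low. These rates also do not measure how far replicate cultures would differ.

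The alternatives were quantile normalization, centring on each array's median, removal of the trend with signal by loess with a span of 0.3, the mean of a gene's probe sets, thresholds of 1.5-fold and 3-fold, other brightness filters, the mean in place of the median of a list, and random lists not matched on signal. Filters on the negative controls and the removal of genes shared between lists were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.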

Results

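Gene expression was measured on whole-transcript arrays in mouse CD8 T cells cultured under Tc1 cytokines, with 1 array of untreated cells and 1 array of cells given cholesterol. The comparison asks which genes differ in expression when cholesterol is added to the culture. Signals ran from 3.24 to 10801 on the untreated array and from 3.74 to 11607 on the cholesterol array, in the authors' linear units. The median gene-level signal was 48.1 without and 46.6 with cholesterol. There were no replicates, so all differences below compare these 2 arrays, and the number of arrays limits the precision.

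Of 11327 genes past the brightness filter, 32 were at least 2-fold higher and 61 at least 2-fold lower with cholesterol. When each array was centred on its own median, a shift of 0.044 on the log2 scale, the split was 45 higher and 45 lower. At a threshold of 1.5-fold the split leaned the other way, with 365 genes higher and 308 lower. Across these 11327 genes, which are not replicates, log2 signals correlated with Pearson's r = 0.982 and Spearman's rho = 0.979, and the median absolute log2 difference was 0.16. The difference narrowed with signal. With these genes in 5 bands of signal, its central 95% ran from -0.88 to 0.76 in the dimmest band and from -0.34 to 0.45 in the brightest. Model-number genes made up 2 of the higher and 5 of the lower genes. Of the 2-fold genes, 12 higher and 36 lower had signals at or below the 95th percentile of the negative controls on both arrays.

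**Figure D1:**
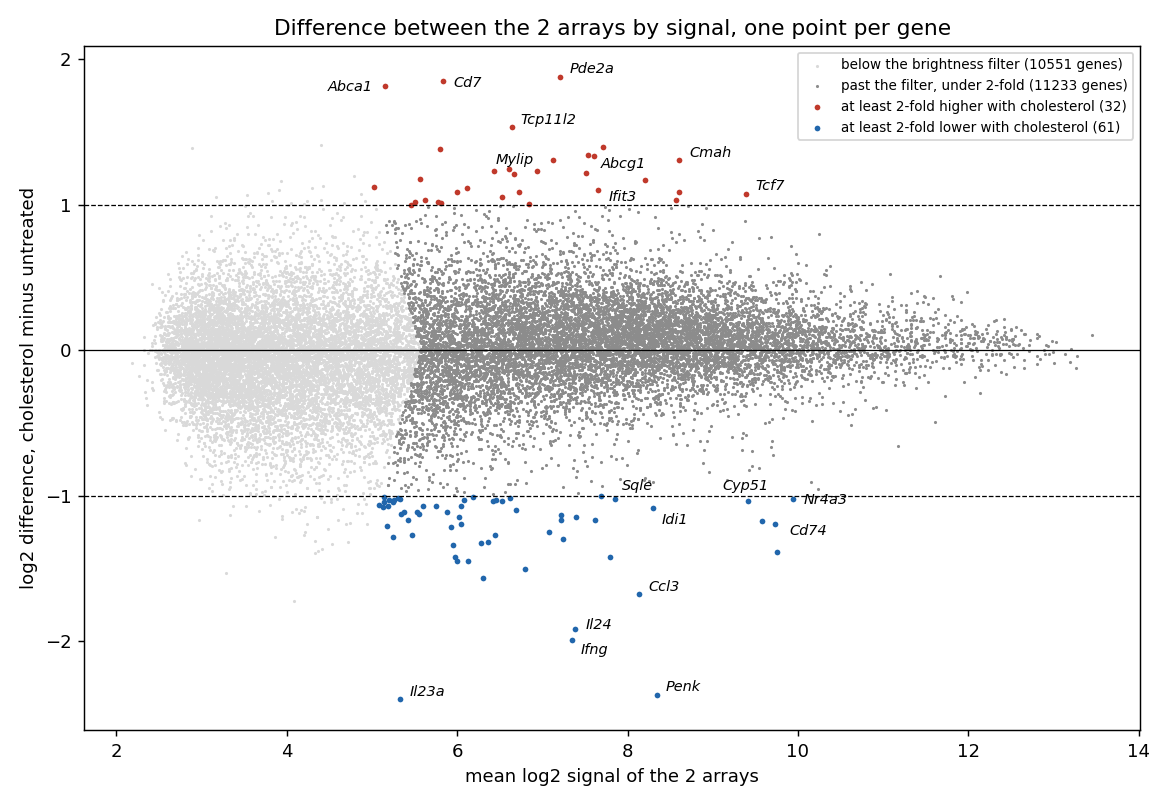
Each point is a gene, with the mean log2 signal of both arrays on the x axis and the log2 difference, cholesterol minus untreated, on the y axis. Dashed lines mark 2-fold, and 32 genes lie at or above the upper line and 61 at or below the lower line past the brightness filter. Penk and Il23a lie lowest, and Il23a is within the range of the negative controls on both arrays.

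The 10 genes with the largest positive difference included 3 targets of the liver X receptor (LXR), a nuclear receptor activated by oxysterols. Abcg1, a sterol exporter, was at least 2.26-fold higher, and Mylip, a ubiquitin ligase, at least 1.69-fold higher. Abca1, a cholesterol efflux pump, had signals of 19.0 without and 67.0 with cholesterol. Pde2a, a cyclic nucleotide phosphodiesterase, had signals of 77.4 and 284.3, which is at least 2.18-fold higher. Tmem71 (at least 2.62-fold), Pik3ip1, an inhibitor of PI3 kinase (at least 2.37-fold), Tcp11l2 (at least 1.30-fold) and Cmah, an enzyme of sialic acid synthesis (2.47-fold), were also in the set. Cd7, a T cell surface protein, had signals of 29.9 and 107.9, and Itgae, the integrin alpha chain CD103, of 34.3 and 89.7. Abca1, Cd7 and Itgae stayed within the range of the negative controls on both arrays. All but Cmah were within it without cholesterol, so the order of these genes is not determined.

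The 10 genes with the largest differences in the other direction included the cytokine genes Il23a, Ifng and Il24. Il23a, the p19 subunit of interleukin 23, had signals of 92.6 without and 17.6 with cholesterol, both within the negative control range. Penk, the precursor of enkephalin peptides, went from 738.2 without to 143.2 with cholesterol, which is 5.15-fold lower. Ifng, the type 1 cytokine interferon gamma, was at least 2.65-fold lower, from 323.2 to 81.5, and Il24, a cytokine of the interleukin 10 family, was at least 2.66-fold lower, from 324.6 to 86.2. Ccl3, a chemokine of activated T cells and macrophages, was 3.20-fold lower. Transglutaminase 2 (Tgm2) was 2.68-fold lower, Mmp12, a metalloprotease of macrophages, at least 1.53-fold lower and Cpa3, a mast cell protease, at least 1.11-fold lower. Cd180, a receptor of B cells and macrophages, and the transcription factor Etv5 lay within the negative control range on both arrays, each at a log2 difference of -1.44.

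Genes of cholesterol synthesis were lower together in the cholesterol array. All 19 measured enzymes of the mevalonate and sterol pathway, which SREBP2 controls and sterols repress, were lower, 10 of them by at least 1.5-fold and 4 by at least 2-fold. The list's median log2 difference was -0.60, a 1.51-fold lower level, and lay below all 10000 matched random lists, whose central 95% ran from -0.041 to 0.18. Idi1 was 2.12-fold lower, Cyp51 2.05-fold and Sqle, squalene epoxidase, 2.03-fold, and Hsd17b7 went from a signal of 291.8 to 145.9. Hmgcs1, the synthase that makes HMG-CoA, was 1.87-fold lower, from a signal of 1554 to 831.

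Genes of sterol uptake and sensing did not share 1 direction. Insig1, which retains SREBP in the endoplasmic reticulum, was 1.34-fold lower, while 7 of the 13 members were higher and 6 lower. Insig2 (0.61) was higher by over 1.5-fold, but it lay below the brightness filter and within the negative control range. Among the 10 members past the brightness filter, 1 was at least 1.5-fold lower and 0 were at least 1.5-fold higher. The list's median was 0.072 and its mean -0.039, the median lay at percentile 65.4 of matched random lists, and over members past the brightness filter it was -0.015. Of 13 genes in the list of LXR targets and sterol efflux, which also holds the receptor genes Nr1h2 (0.14) and Nr1h3 (0.012), 12 were higher, 3 of them (Abca1, Abcg1 and Mylip) by at least 2-fold in the deposited signals and Smpdl3a (0.88) by over 1.5-fold. Their median log2 difference was 0.33, at percentile 99.96, with a central 95% of -0.12 to 0.20 for random lists. Fatty acid synthesis genes had a median of -0.056 at percentile 3.87, but of -0.0051 at percentile 43.6 after quantile normalization and -0.015 at percentile 40.1 after loess, and of -0.012 after centring, with Fads2, a fatty acid desaturase, at -0.72 and Acaca, acetyl-CoA carboxylase, at 0.43. Fatty acid uptake and oxidation genes had a median of -0.014 (percentile 19.4), or 0.030 after centring each array on its median, with Fabp5 at -0.49 and Cpt2 at 0.39.

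**Figure D2:**
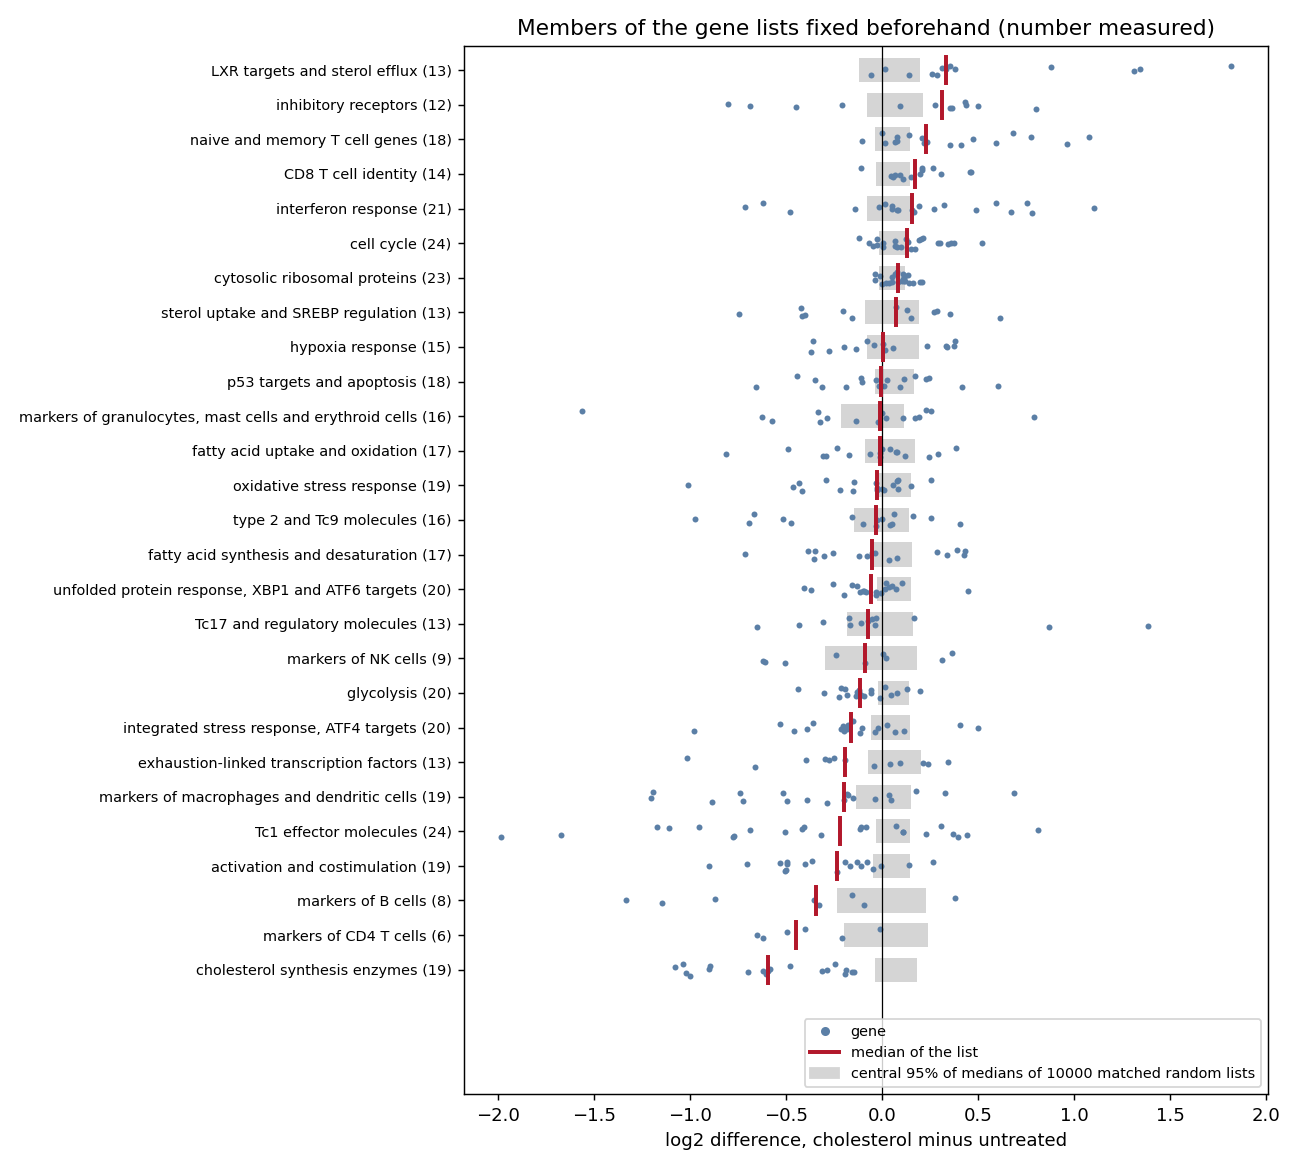
Each row is a gene list fixed beforehand, each point a measured member, and the x axis gives the log2 difference, cholesterol minus untreated. Red bars are list medians and grey bars the central 95% of medians of 10000 matched random lists, and the enzymes of cholesterol synthesis (median -0.60) and the LXR and sterol efflux genes (median 0.33) lie at the ends.

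Genes of the Tc1 effector program were mostly lower with cholesterol. Of 24 measured members, 15 were lower, 8 of them by at least 1.5-fold and 4 by at least 2-fold, while Klrk1 was at least 1.5-fold higher. The list's median log2 difference was -0.22, below all 10000 matched random lists. Beside Ifng and Ccl3, the 2-fold lower genes were Lta, lymphotoxin alpha (-1.18), and Ccl4 (-1.11, within the negative control range), and Gzma, granzyme A, differed by -0.96. Prf1, the pore-forming protein perforin, was 1.71-fold lower and Tnf was 1.61-fold lower. Gzmb, granzyme B, had signals of 8464 without and 7983 with cholesterol, a log2 difference of -0.084. Tbx21, the transcription factor T-bet, differed by 0.11, and Klrk1, the receptor NKG2D, by 0.81. Restricted to members above the negative controls, the median was -0.12 at percentile 0.01. In the same pair of arrays, B cell markers past the brightness filter were also lower, with a median of -0.87, as were those of macrophages and dendritic cells, with a median of -0.52.

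Of the 16 type 2 and Tc9 genes, Il13, Csf2 and Spi1 (-0.67) were past 1.5-fold lower in the deposited signals. Spi1 lay within the negative control range with cholesterol. Of the 13 Tc17 and regulatory genes, Itgae and Smad7 were past 1.5-fold higher and Foxp3 lower. Itgae, Smad7 and Foxp3 lay within the negative control range on both arrays. Il9 had a signal of 26.7 on each array, within the negative control range. In the type 2 and Tc9 list, Il13 was at least 1.09-fold lower, Csf2 (-0.70) lay within the negative control range on both arrays, and the list's median of -0.031 (0.013 after centring each array on its median) lay at percentile 29.6. Over the 8 members of that list past the brightness filter, the median was -0.29 at percentile 0.19. In the Tc17 and regulatory list, Smad7, an inhibitor of TGF-beta signalling, was at 0.87, the median was -0.074 (-0.030 after centring) and the mean 0.027, and the median lay at percentile 19.4.

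Inhibitory receptors differed in both directions. Lag3 was 1.74-fold higher, Tigit 1.41-fold, Ctla4 1.28-fold, Pdcd1, which encodes PD-1, 1.27-fold, and Cd244, which encodes 2B4, 1.21-fold, while Havcr2, which encodes TIM-3, was at least 1.39-fold lower. Of 12 receptors, 8 were higher and 4 lower, with Lag3 past 1.5-fold higher and Havcr2 (-0.81) and Entpd1 (-0.69) past 1.5-fold lower in the deposited signals. The median of 0.31 lay at percentile 99.93 of matched random lists, but the mean of 0.090 lay at percentile 65.5. Of 13 transcription factors linked to exhaustion, 8 were lower, and their median was -0.20 at percentile 0.05, with Nr4a3, an early gene of T cell receptor signalling, 2.03-fold lower and Eomes 1.58-fold lower.

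Naive and memory T cell genes were mostly higher with cholesterol and activation genes mostly lower. Of 18 naive and memory genes, 16 were higher, and the median of 0.23 lay at percentile 99.97. Tcf7, which encodes the transcription factor TCF-1 of naive and memory cells, went from 462.1 to 972.2, a 2.10-fold higher level. Klf2, which controls T cell migration, was 1.95-fold higher, and S1pr1 (0.77) and Id3 (0.68, within the negative control range without cholesterol) were also past 1.5-fold higher. Bcl6 (0.59) lay below the brightness filter and within the negative control range on both arrays. Of 19 activation and costimulation genes, 17 were lower, Cd86 (-0.91, within the negative control range) and Egr3 by at least 1.5-fold, and the median of -0.24 lay below all 10000 matched random lists. Egr3, an early growth response factor, was 1.63-fold lower on its brightest probe set, but its 3 probe sets ran from -0.71 to 0.14. Nfkbiz was 1.45-fold lower. The B cell and macrophage markers with medians of -0.87 and -0.52 past the brightness filter were lower in the same pair of arrays. Cell cycle genes had a median of 0.13 at percentile 96.5 (0.065 after quantile normalization and 0.068 after loess), with Bub1 at 0.52 and Foxm1 at 0.37.

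**Figure D3:**
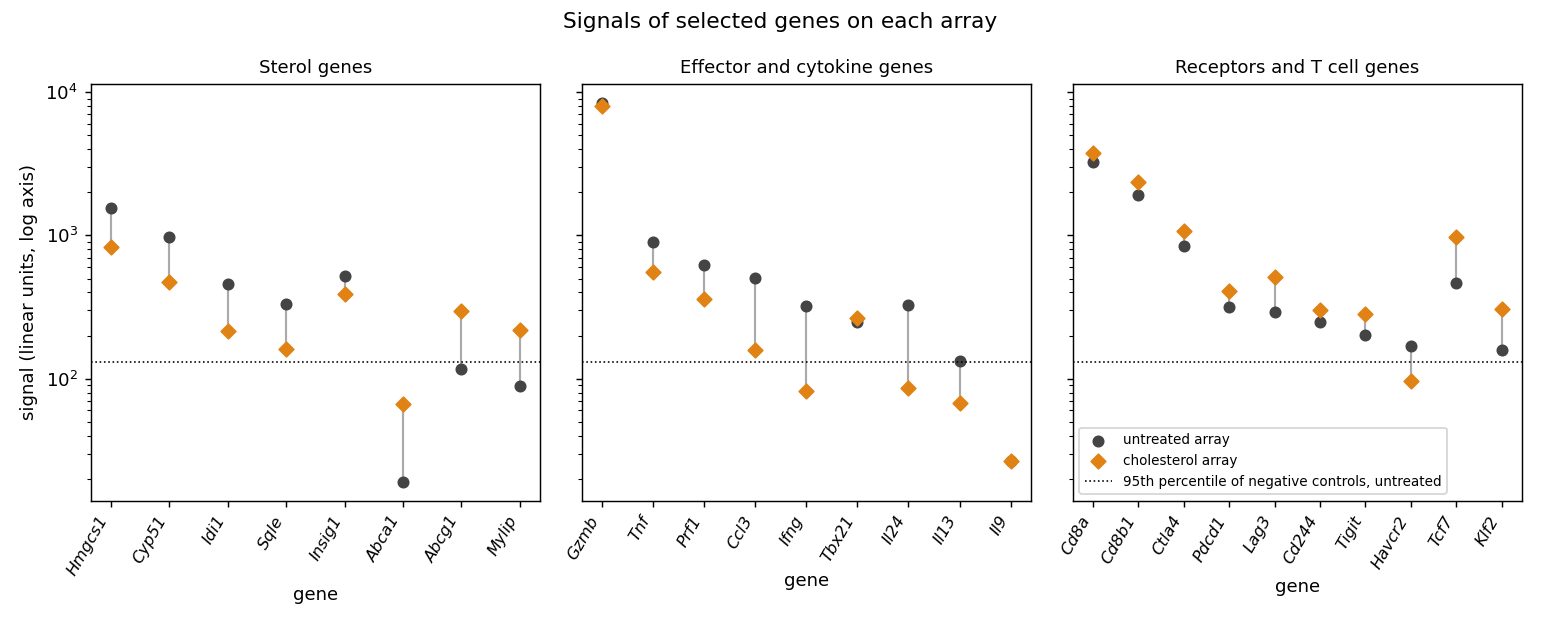
The signals of selected sterol, effector and receptor genes are plotted on a log axis, with a circle for the untreated and a diamond for the cholesterol array, and a dotted line at the 95th percentile of the untreated array's negative controls (130.3). Hmgcs1 lies lower with cholesterol (1554 to 831) and Tcf7 higher (462.1 to 972.2), while Gzmb (8464 and 7983) and Cd8a differ little.

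Most targets of ATF4 (15 of 20) and glycolysis genes (15 of 20) were lower with cholesterol. Targets of XBP1 and ATF6 in the unfolded protein response had a median of -0.060 at percentile 0.40, with 13 of 20 lower, but after centring the median was -0.016 with 10 higher and 10 lower, and after quantile normalization -0.12 with 18 lower. No member reached 1.5-fold, with Xbp1 at 1.33-fold lower and the chaperone gene Dnajb9 at 0.44, within the negative control range on both arrays. Targets of ATF4 had a median of -0.17, below all 10000 matched random lists, with Atf3 at least 1.97-fold lower and Pck2 1.41-fold higher. Glycolysis genes had a median of -0.12 at percentile 0.02 (-0.074 after centring), with Hk2, hexokinase 2, at -0.44 and the lactate exporter Slc16a3 at -0.30. Among random lists not matched on signal, the unfolded protein response list lay at percentile 13.6 and the glycolysis list at 3.52, both inside the central 95%. In the oxidative stress list, Hmox1, heme oxygenase 1, was at least 1.15-fold lower and Txnrd1 1.38-fold lower, and the median of -0.030 (0.014 after centring each array on its median, -0.068 after quantile normalization and -0.092 after loess) lay at percentile 3.99. Hypoxia genes (median 0.0040, percentile 26.4, or -0.051 after quantile normalization and -0.059 after loess) held Pdk1 at 0.38 and Egln3 at -0.37. Targets of p53 and apoptosis genes (median -0.0054, percentile 10.9, or 0.039 after centring, -0.061 after quantile normalization and -0.066 after loess) held Gadd45b at -0.66 and Bcl2l11, the death gene Bim, at 0.60. Interferon response genes had a median of 0.15 at percentile 97.8, and at 95.1 after quantile normalization, 97.1 after loess and 92.3 over members above the negative controls. Of its 21 members, 16 were higher, with Ifit3 2.15-fold and Irf7 1.72-fold higher and Oas3 at 0.59, while Irf8 was at -0.62. Oas1a (0.75), Ifit1 (0.67) and Cxcl10 (-0.71) also differed by over 1.5-fold but lay within the negative control range on both arrays.

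T cell identity genes were slightly higher with cholesterol and markers of B cells, of macrophages and dendritic cells and of CD4 T cells were lower. Of 14 identity genes, 13 were higher, with a median of 0.17 at percentile 99.2, and 11 after loess, with a median of 0.11. Cd3d was 1.37-fold higher, Zap70, a kinase of T cell receptor signalling, 1.37-fold, Cd8b1 1.24-fold and Cd8a 1.15-fold, with Cd8a at 3274 without and 3780 with cholesterol. B cell markers had a median of -0.34 at percentile 0.36, with Cd79a at least 2.06-fold lower and 7 of 8 lower, and its immunoglobulin genes Ighm, Ighd and Igkc had no matching symbol. Macrophage and dendritic cell markers had a median of -0.20 at percentile 0.40, with Cd74, the MHC class II chaperone, 2.29-fold lower from 1288 to 562.0 and Mpeg1 at -1.21. Mpeg1, Foxp3 and Hbb-bt lay within the negative control range on both arrays. Over the members past the brightness filter, these medians were -0.87 for B cells and -0.52 for macrophages and dendritic cells. CD4 T cell markers had a median of -0.45 at percentile 0.05, with all 6 lower, Cd4 1.54-fold lower and Foxp3 at -0.66, but without genes that other lists hold it was -0.21 at percentile 6.44. NK cell markers (median -0.089, percentile 33.3, or -0.020 after quantile normalization, -0.045 after centring and -0.038 after loess), with Klri2 at -0.24 and Klrb1c at 0.0024, lay inside the central 95%. So did granulocyte, mast cell and erythroid markers (median -0.011, percentile 64.0, or 0.026 after quantile normalization, 0.033 after centring and 0.021 after loess), with Hbb-bt at -0.57, although Cpa3 of that list was among the 10 genes with the largest negative difference. Cytosolic ribosomal protein genes, the control list, had a median of 0.079 at percentile 79.4 (0.12 after centring and 0.037 after loess) and ran from -0.038 to 0.21, with Rps18 at 0.21 and Rps4x at 0.20.

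In all, 10 of the 27 lists lay below and 5 above the central 95% of matched random lists, against 1.35 expected outside by chance. These percentiles describe this pair of arrays and do not measure how far replicate cultures would differ.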

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

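The test of the control probe sets was chosen after their values had been seen. The 1324 positive control probe sets, which entered no comparison, had a median log2 difference of 0.067, cholesterol minus untreated, with median signals of 259 and 273. This lay above the central 95% of 0.027 to 0.055 for the medians of 1000 random sets of gene-level probe sets of like signal. The 5222 negative controls had a median difference of -0.0016, which was not above the untreated array but lay above their own random range of -0.027 to -0.0089. No explanation was tested for either value.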

How the results depend on the processing

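The filters on negative controls and the removal of genes shared between lists were chosen after seeing the data, and all other alternatives before. With 1 array per group no replicate could be left out, and the series value table held identical values, so it gave no separate alternative. A list's median counted as moved when it shifted by more than the SD of the medians of matched random lists, and a count when it changed by over 1.5 times. None of the lists outside the central 95% and none of the named genes at or past 1.5-fold turned its direction under the alternatives run. Of 328 values of the 82 named genes under alternatives, 1 moved, that of Egr3 to -0.35 with the mean of its probe sets. The medians of 6 lists inside the central 95% changed sign under a scaling, namely fatty acid oxidation, type 2 and Tc9, oxidative stress and p53 targets, hypoxia, and granulocyte, mast cell and erythroid markers. The number of lists outside the central 95% was 15 and ranged from 14 to 16. Lists with under 3 members left gave no value, which left out NK cell markers under both filters on members and B cell and granulocyte, mast cell and erythroid markers under the negative control filter. The causes of the moves below were not tested. For dim genes the signal over background is the limit, since 35.6% of all genes had an array above the 95th percentile of its negative controls.

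The counts of 32 higher and 61 lower genes became 365 and 308 at 1.5-fold, 3 and 5 at 3-fold, 51 and 109 with no brightness filter, 20 and 29 with both arrays past it, 12 and 18 with it at the 75th percentile, and 20 and 25 with the negative control filter. Quantile normalization moved cholesterol synthesis to -0.66, inhibitory receptors to 0.235, the unfolded protein response to -0.12, ATF4 targets to -0.22, cell cycle to 0.065, glycolysis to -0.16, p53 targets to -0.061 and CD8 identity to 0.12. Centring on the median moved cell cycle to 0.17, glycolysis to -0.074 and ribosomal proteins to 0.12. Loess moved cholesterol synthesis to -0.67, inhibitory receptors to 0.24, the unfolded protein response to -0.12, ATF4 targets to -0.23, activation to -0.29, cell cycle to 0.068, oxidative stress to -0.092, p53 targets to -0.066, CD8 identity to 0.11 and ribosomal proteins to 0.037.

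With only members past the brightness filter, medians became -0.015 for sterol uptake, -0.29 for type 2 and Tc9, -0.87 for B cells, -0.52 for macrophages and dendritic cells and -0.33 for granulocyte, mast cell and erythroid markers. With only members above the negative controls, they became -0.015 for sterol uptake, 0.032 for fatty acid synthesis, 0.072 for fatty acid oxidation, -0.12 for Tc1 effectors, -0.29 for type 2 and Tc9 and -0.52 for macrophages and dendritic cells. Means in place of medians were -0.039 for sterol uptake, 0.57 for LXR and sterol efflux genes, 0.090 for inhibitory receptors, -0.35 for Tc1 effectors, -0.17 for type 2 and Tc9, 0.027 for Tc17, 0.35 for naive and memory, -0.29 for activation, -0.13 for oxidative stress, -0.49 for B cells, -0.31 for macrophages and dendritic cells and -0.13 for granulocyte, mast cell and erythroid markers. Without shared genes the CD4 list was at -0.21. The interferon list moved inside the central 95% under quantile normalization, loess and the negative control filter, inhibitory receptors with means, the CD4 list without shared genes, and the unfolded protein response and glycolysis lists without matching on signal. The type 2 and Tc9 list moved outside under both filters, oxidative stress with means, and cell cycle without matching.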

Other observations

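The gene families, the annotation terms and all tests in this part other than those after loess were chosen after the results were seen, the test of a sterol response included; the tests after loess were set down before their values were computed but with the unadjusted values known. Each family took in only its members past the brightness filter. A dim member can pass it on 1 array alone, which favours members with a large difference, so the family percentiles are descriptions and not tests. Only without cholesterol did Ccl4, Ccl11, Ccl9, Cxcl10, Gzmg, Gzmn, Il23a, Il17a, Klri2 and Oas1g pass it, and only with cholesterol Oas1a and Hist4h4. Of 14 chemokine ligands past the brightness filter, 12 were lower with cholesterol and the median log2 difference was -0.56, below all 10000 matched random lists. Ccl3 (-1.68), Ccl22 (-1.17) and Ccl4 (-1.11) were past 2-fold lower in the deposited signals, while Ccl5 was at 0.44. All but Ccl3, Ccl22, Ccl5 and Ccl25 lay within the negative control range on both arrays. Of the chemokines above that range on both arrays, Ccl3 was lower, Ccl5 higher and Ccl25 equal. In the same pair of arrays, macrophage and dendritic cell markers past the brightness filter were also lower, with a median of -0.52. All 7 granzymes past the brightness filter were lower as deposited and under each scaling run. Their median was -0.66 as deposited, below all 10000 matched random lists. Gzmk, below the brightness filter, was at 0.23. Gzmd was at -0.66 with a signal of 2906 without cholesterol, Gzmf was at -1.13 and Gzmg at -1.42, while Gzmb was nearest to 0, at -0.084. Gzmg and Gzmn lay within the negative control range on both arrays and Gzmf with cholesterol. Gzmd, Gzmf and Gzmg are similar copies whose probes can share targets, so their single values are uncertain. Of 9 MHC class II genes, 7 were lower as deposited and 8 after quantile normalization or loess, with a median of -0.52 as deposited, below all 10000 matched random lists, while H2-Oa was at 0.51. Of 6 interleukin genes past the brightness filter, 5 were lower as deposited and 4 after quantile normalization or centring. Their median was -0.74 at percentile 0.01, and Il23a and Il24 were past 2-fold lower in the deposited signals. Il23a and Il17a lay within the negative control range on both arrays, and Il24, Il13 and Il17b with cholesterol. Il16, above that range on both arrays, was at 0.18. The fixed lists already held 5 of these chemokines, 3 of the granzymes, 4 of the MHC class II genes and 2 of the interleukins.

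In the other direction, 14 of 16 IFIT, IFITM and OAS genes, from families that interferon induces, were higher as deposited and under each scaling run, with a median of 0.41, above all 10000 matched random lists. Ifit3 (1.10) and Ifit1bl1 (1.06) had the largest differences as deposited, and 7 of the 16 are in fixed lists. Ifit1bl1, Ifit3b and Ifitm7 lay within the negative control range without cholesterol, so the order of these genes is not determined. Oas1g, Ifit2, Oas2, Oas1c, Ifit1 and Oas1a lay within the negative control range on both arrays. Similar copies such as Ifit3 and Ifit3b can share signal. All 18 genes of MHC class I and its peptide loading were higher as deposited, but their median of 0.15 lay at percentile 97.3, inside the central 95%, and 13 were higher after quantile normalization (median 0.075) and 14 after loess (median 0.086). Of 60 histone genes, 57 were higher as deposited, with a median of 0.11 at percentile 99.95, and 50 after quantile normalization (median 0.057) and 51 after loess (median 0.067). Several histone copies, such as Hist1h2ao and Hist1h2ap, carry identical signals. Of 7 killer cell lectin-like receptors, 5 were higher as deposited and 4 after loess, with a median of 0.042 at percentile 56.6. They ran from Klrb1b at -0.38 to Klrd1, which encodes CD94, at 1.09. At least 1.5-fold, 3 were higher and 0 lower. Klrd1 lay above the negative control range on both arrays and Klrk1 (0.81) with cholesterol, and the others lay within it on both. Among 1440 biological process terms of the deposited annotation with 10 to 200 genes, 54 lay below the 0.5 percentile of matched random lists and 16 above the 99.5 percentile, against 7.2 expected in each tail. Terms such as cholesterol, sterol and steroid biosynthetic process overlap in their genes. The terms are therefore not independent, and the excess over 7.2 is not a count of separate differences. Cholesterol biosynthetic process (median -0.40, 22 genes) was the farthest below in units of the random spread, followed by cytolysis (-0.51, 15 genes), and the farthest above were cilium morphogenesis (0.18, 50 genes), regulation of innate immune response (0.35, 10 genes) and mitotic spindle assembly checkpoint (0.27, 16 genes). Many of the cilium genes lay within the negative control range on both arrays. Among them, Ift172, Ttc21b and Ift88 reached the brightness filter only with cholesterol, and Tekt3 only without it. The rank of the cilium term is therefore uncertain.

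Enzymes of cholesterol synthesis were lower while genes of the LXR and sterol efflux list were higher. After loess the median of that list lay 0.98 above the enzyme median, against a central 95% of -0.19 to 0.19 for pairs of random lists, which argues against a trend with signal. Macrophage and dendritic cell markers past the brightness filter had a median of -0.52 with 9 of 11 lower. They cannot decide whether there was more macrophage RNA with cholesterol. Lyz2, Mpeg1, Fcgr3 and Itgam lay within the negative control range on both arrays. The MHC class II genes among them can also come from B cells, whose markers were lower too. Of the other markers, Cd68 was at 0.32, Ctss at 0.042 and Fcer1g at -0.74. A response to the added sterol is a hypothesis that needs both lists beyond their random ranges in these directions, which they were, with a gap of 0.93 as deposited (random central 95% -0.22 to 0.17), but this gap had been seen before the test was written. A difference between the cultures unrelated to cholesterol cannot be told apart from it with 1 array per group.

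Type 1 effector genes were lower while naive and memory genes were higher. After loess the gap between both medians was 0.41, beyond the central 95% of -0.13 to 0.13 for random pairs, which argues against a trend with signal. A smaller share of other cells would raise T cell genes together, but the effector median lay -0.39 from the identity median (random central 95% -0.13 to 0.13). Without Ccl3, Ccl4 and Tnf, which macrophages also make, it lay -0.28 from it. This argues against a smaller share of cells that make few effector genes. It cannot decide on a smaller share of other T cells, which share the identity genes apart from Cd8a and Cd8b1. Cd4 was 1.54-fold lower, while Zbtb7b of the same list was at -0.011. A smaller share of other cells may account for the median of the naive and memory genes. That median differed from the identity median by 0.055, inside the random central 95% of -0.13 to 0.13. These medians do not cover the largest differences. No identity gene reached 1.5-fold (highest 0.46), while Tcf7 (1.07), Klf2 (0.96), S1pr1 (0.77) and Id3 (0.68) did. For the naive and memory genes, a smaller share of other cells is therefore left open for the list's median only. For the effector genes, a smaller share of other cells that make them, such as other T cells, stays open. Weaker activation of the cholesterol culture and a difference between the cultures unrelated to cholesterol also stay open, since the activation list's median of -0.24 lay below all 10000 matched random lists, while inhibitory receptors, which activation induces, had a median of 0.31 at percentile 99.93 (mean 0.090 at percentile 65.5), and 19 of 24 cell cycle genes (15 after loess) and 57 of 60 histone genes (50 after quantile normalization) were higher.

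B cell and MHC class II genes were lower with cholesterol. The median of 16 B cell, macrophage and dendritic cell markers past the brightness filter was -0.62 as deposited and -0.65 after loess, which argues against a trend with signal. A smaller share of B cells and antigen presenting cells could account for it, and 87.5% of these markers (14) were lower, none of them in another fixed list and with no sort or gate named in the labels, but Cd68 was at 0.32 and Ctss, with signals of 525 and 541, at 0.042 (-0.027 after loess). Among the brightest markers, Cd74 went from 1288 to 562.0 and H2-Ab1 from 441 to 308, while the immunoglobulin genes, abundant in B cells, were not analysed here. A smaller share of such cells and a lower level within the T cells cannot be told apart, since the arrays measured bulk RNA.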
